A study of Mus musculus with 12 samples.

How the data were processed

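Total RNA was extracted with Trizol and made into biotin-labelled cRNA by the standard Affymetrix procedure, per the labels' protocols. The submitters' processing notes name RMA, a method that corrects background, normalizes and summarises the probes of each probe set. The array name, the software version, the hybridisation batches and any filter are not given in the sources used here. The deposited values were 1 table of 1246 probe sets by 12 samples, on a log2 scale (from the values, which run from about 2 to 13 with no zero). The columns did not share a single distribution, so repeated quantile normalization was run as an alternative and not as the main setting. RMA values carry no detection call, and the number of arrays limits the precision.

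Probe set identifiers were matched, without version numbers, to the accessions of a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of the 1246 probe sets, 984 carried a RefSeq accession, 261 a UCSC transcript identifier and 1 another identifier. In all, 963 probe sets matched 1 symbol, 0 matched several and 283 matched none; the last are unnamed here. A gene with several probe sets (48 genes) was represented by the probe set with the highest mean over all samples. No coordinates are given.

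Groups and replicate numbers were taken from the titles. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples, which may be technical. The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the deposited log2 values of all 12 samples with group means and no covariate, with Benjamini-Hochberg adjustment over 1246 probe sets and a threshold of 0.05. The replicated comparisons were 2 h against non-wounded, 30 min against non-wounded and 2 h against 30 min. Single samples at 0 h and 4 h were compared with the mean and range of the 4 non-wounded samples, and a difference of 1 or more on the log2 scale outside that range was described. Gene lists fixed in advance (28 gene lists and 8 cell type marker lists) were tested with camera at its preset correlation of 0.01, two-sided, on 1 probe set per gene, where 3 or more genes were measured, which held for 32 lists. Camera with an estimated correlation and fry were alternatives.

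The genes given by name followed a rule fixed before the data were examined. It took up to 12 genes per direction past the threshold, or the 10 with the smallest p where fewer passed, up to 4 called members of each list or 2 with the smallest p, the 8 largest differences per direction of the single samples, and 15 measured genes of wound responses named in advance. Genes called only with the replicate block are named as such. Some genes that the rule takes are not reported here.

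The replicate numbers of the titles were checked as a pairing. Deviations from the group means of the 2 h and non-wounded samples with the same number correlated across probe sets at 0.796, 0.449, 0.651 and 0.297 for numbers 1 to 4, all above the limit of 0.1 set in advance, so blocked values stand beside the results they change. Number 1 was the one number whose samples correlated best with each other. With the samples numbered 1 left out, the correlations for numbers 2 to 4 were -0.150, 0.0727 and -0.319, so the block mostly removes a difference between number 1 and the rest.

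Other alternatives were repeated quantile normalization, median centring, a filter on probe sets under the 25 percentile of mean level, an intensity trend with a robust prior, array weights, 1 probe set per gene, a random replicate block, only the groups compared, a threshold of 0.01, a log2 fold change of 1 or more and leaving out each sample. Added after the data were seen were a term for the samples numbered 1, the samples numbered 2 to 4 alone, scaling each sample to one median and SD, quantile normalization with the replicate block, and the non-wounded sample numbered 1 as the reference for 0 h and 4 h, also with that scaling. An alternative with control and other-species probe sets was not run, because the table held 0 control probe sets and the setting would change nothing.

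The fits were tested on simulated data for 2 h against non-wounded, with the real means, the shift of the samples numbered 1 and the residual spread, and 200 of 1246 probe sets changed at 2 h. For changes of 1 on the log2 scale the main design recovered 60.3% and the blocked design 91.3%; for changes of 2 they recovered 88.6% and 99.5%. Of the calls, 0.40% and 4.07% were false. The simulation gave all samples numbered 1 the same shift and the same 2 h change as the others, with independent noise. In the real data the largest 2 h rises were smaller in the pair numbered 1, so these rates hold for the simulated setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.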

Results

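Gene expression was measured by single-colour arrays in mouse samples taken without wounding and at several times after it, to find genes whose level changes early after injury. The design text plans RNA from whole epidermis, a tissue made mostly of keratinocytes, the cells that form the skin barrier. The sample labels instead name dendritic epidermal T cells, the resident T cells of mouse epidermis, so the material is stated in 2 ways. There were 12 samples: 4 non-wounded, 1 at 0 h, 2 at 30 min, 4 at 2 h and 1 at 4 h after wounding. The values covered 1246 probe sets, of which 963 were named, for 909 genes, many of them glycan-processing enzymes, lectins, cytokines and their receptors. In the non-wounded samples the keratinocyte galectin Lgals7 had a log2 value of 12.08 ± 0.27 (SD, n = 4), the Langerhans cell lectin Cd207 7.86 ± 0.63 and the activating receptor Klrk1 2.38 ± 0.12. The Lgals7 and Cd207 values argue against T cells alone in these 4 samples. The share of each cell type is left open here.

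The 5 samples numbered 1 in the titles, 1 from each group, stood apart from the other 7. Their log2 values had an SD over probe sets of 1.55 to 1.85, against 2.19 to 2.30 in the samples numbered 2 to 4, and the first principal component, with 66.9% of the variance, separated the 2 sets. The 5 were not uniform: their lowest correlation with each other was 0.916, below the highest across the 2 sets (0.938). The non-wounded and 0 h samples numbered 1 correlated at 0.981, with SDs of 1.81 and 1.85. Those at 30 min, 2 h and 4 h had SDs of 1.56, 1.59 and 1.55. Their differences from the non-wounded sample numbered 1 therefore also hold this narrower range, which a single term for number 1 does not remove. The 0 h and 4 h groups held only a sample of this kind, the 30 min group held 1 of each kind, and the non-wounded and 2 h groups held 1 and 3.

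**Figure D1:**
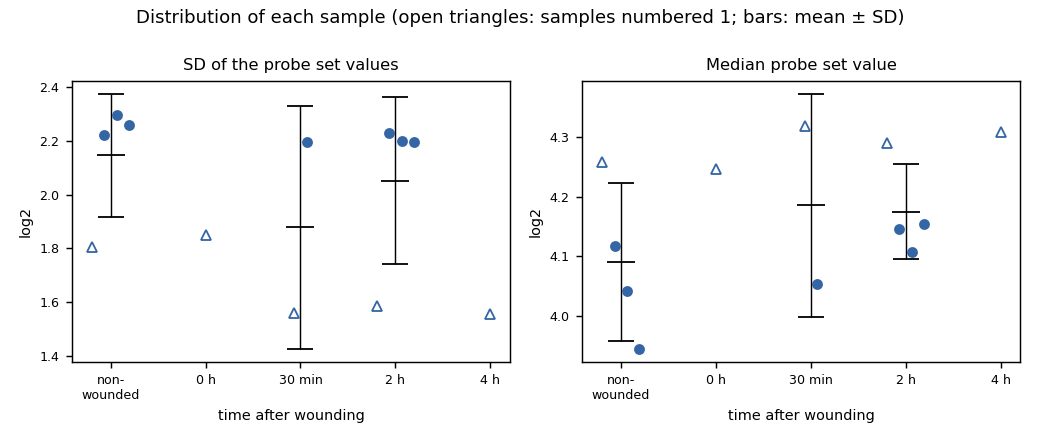
SD (left) and median (right) of the log2 probe set values of each sample, by time after wounding; points are samples, open triangles those numbered 1, and bars the mean ± SD of groups with 2 or more samples. The 5 triangles lie at an SD of 1.85 or less and the other 7 samples at 2.19 or more.

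The first comparison asked which genes differed between the samples taken 2 h after wounding and the non-wounded samples. Hbegf, a growth factor of the EGF family that acts on keratinocytes, rose 9.05-fold (log2 fold change 3.18 ± 0.47 SE, limma adjusted p = 0.0376). Ccl20, the chemokine ligand of CCR6, rose 17.1-fold (log2 4.09 ± 0.65, adjusted p = 0.0412). Another probe set, NM_020008.1_psr1_at, which is not named here, rose 4.83-fold (log2 2.27 ± 0.33, adjusted p = 0.0376). For each of these, all 4 samples at 2 h lay outside the range of the 4 non-wounded samples.

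With the replicate number as a block, 17 probe sets passed instead of 3, with 14 higher and 3 lower, and the 3 probe sets above were among them (adjusted p = 0.00953 for Hbegf and 0.0265 for Ccl20). The balance differed in other fits, with 13 higher and 0 lower for quantile normalization with the block and 60 higher and 70 lower with array weights. The blocked fit added the neutrophil-attracting chemokines Cxcl2 (log2 3.13, adjusted p = 0.0297 with the block and 0.0777 without) and Cxcl1 (2.40, 0.0463 and 0.16). It also added the adhesion molecule Icam1 (2.56, 0.0114 and 0.0777), the AP-1 subunit Junb (1.74, 0.0448 and 0.354), the EGF family ligand Areg (1.39, 0.0297 and 0.087) and the angiogenic factor Vegfa (1.23, 0.0265 and 0.087). Further rises in that fit were those of Uap1, which makes UDP-N-acetylglucosamine (1.11, 0.0448 and 0.998), the chemokine Ccl21a (0.96, 0.0448 and 0.707), Cd207 (0.91, 0.0448 and 0.998) and the receptor Havcr2 (0.79, 0.0448 and 0.144). The receptor subunit Il20rb fell by 1.03 on the log2 scale (0.0448 and 0.998). The other 3 added probe sets were unnamed, and of them uc007bsm.1_psr1_s_at rose (log2 3.78, 0.0265 and 0.0649) and 2 fell. In the samples numbered 2 to 4 alone Ccl21a, Cd207 and Il20rb did not pass (adjusted p = 0.103, 0.101 and 0.0835). With quantile normalization and the block Cxcl1, Havcr2, Ccl21a and Il20rb did not (0.114, 0.179, 0.212 and 0.0659). With a random replicate block Uap1, Ccl21a, Cd207 and Il20rb did not (limma adjusted p = 0.0966, 0.0506, 0.115 and 0.133). Among the 10 named genes with the smallest p without the block, B4galt5, a galactosyltransferase of lactosylceramide synthesis, was at log2 0.86 (adjusted p = 0.16) and the fucosyltransferase Fut1 at -1.01 (0.171).

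**Figure D2:**
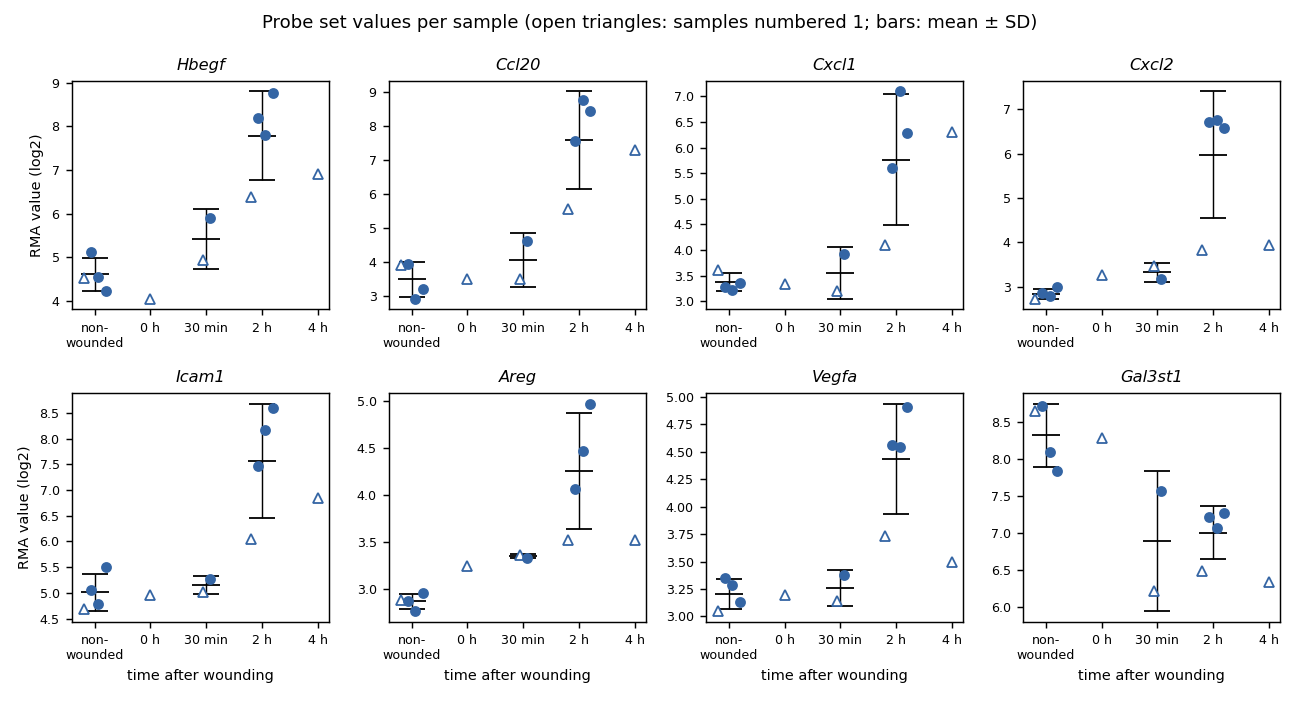
Log2 values of 8 genes in each of the 12 samples by time after wounding; points are samples, open triangles those numbered 1, and bars the mean ± SD of groups with 2 or more samples. For Hbegf, Ccl20, Cxcl1, Cxcl2, Icam1, Areg and Vegfa all 4 samples at 2 h lie above the non-wounded samples, and the 2 h sample numbered 1 is the lowest of the 4 for Cxcl2, at 3.83.

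Hbegf, Ccl20, Cxcl2, Cxcl1 and Icam1 were higher at 2 h in both kinds of sample, by less in the pair numbered 1. In the samples numbered 2 to 4 alone, fitted after the data were seen, the log2 difference was 3.62 for Hbegf, 4.91 for Ccl20, 3.80 for Cxcl2, 3.04 for Cxcl1 and 2.95 for Icam1, and 38 probe sets passed, 23 higher and 15 lower. Between the pair numbered 1 the differences were 1.86 for Hbegf, 1.65 for Ccl20, 1.10 for Cxcl2, 0.47 for Cxcl1 and 1.37 for Icam1, with no replicate. Without the block, 58 probe sets had an unadjusted p under 0.05. No probe set passed when 1 non-wounded sample or 1 of 2 h replicates 2 to 4 was left out, or when samples were centred on their medians (Hbegf 3.09, adjusted p = 0.124), and 11 passed without 2 h replicate 1.

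Among the genes named in advance whatever their value, the others did not pass in either fit. The inflammatory cytokine Il1b was at log2 1.26 (adjusted p = 0.354), Il6 at 1.01 (0.354) and Il1a at -0.41 (0.998). Of the hyaluronan synthases, Has3 was at 1.40 (0.707), Has2 at 0.68 (0.789) and Has1 at 0.32 (0.998). The hyaluronan receptor Cd44 was at 1.02 (0.998), the proteoglycan Sdc1 at -0.54 (0.998) and Klrk1 at -0.05 (0.998).

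Of the 32 lists with 3 or more measured genes, 8 passed at 2 h by limma's camera test with its preset correlation. Chemokines were shifted up (adjusted p = 0.00162, or 0.473 with an estimated correlation), with 24 of 29 measured members higher and a median of 0.13, or 16 of 29 and 0.0023 with each sample scaled to one median and SD. Of the 29, 1 rose (Ccl20) over all probe sets and 3 adjusted over the list alone, while with the block 4 rose by either adjustment (Ccl20, Cxcl2, Cxcl1 and Ccl21a over all probe sets). Adhesion molecules were shifted up (adjusted p = 0.0103, or 0.285 with an estimated correlation), with 11 of 12 members higher; none rose over all probe sets and 1 rose adjusted over the list alone, or 1 and 2 with the block. The EGF family was shifted up (adjusted p = 0.034, or 0.285 with an estimated correlation, and 0.227 with the block). Its mean log2 change was 0.67 and its median was -0.04, with Hbegf and Areg at 3.18 and 1.39, and 1 of 6 members rose over all probe sets and 2 adjusted over the list alone. Genes of hyaluronan synthesis, turnover and binding were shifted up (adjusted p = 0.034, or 0.285 with an estimated correlation), with 6 of 7 members higher and none past the test, over all probe sets or adjusted over the list alone, while 2 rose adjusted over the list alone with the block. With 1 sample left out, the chemokine list passed each time (1.85e-04 to 0.0355) and the adhesion list each time but without 2 h replicate 1 (0.062). The hyaluronan list did not pass without 2 h replicate 1 (0.062), non-wounded replicate 1 (0.0687) or 2 h replicate 3 (0.0693). The EGF family did not without non-wounded replicates 1 or 3 (0.112 and 0.0527) or 2 h replicates 2 or 3 (0.0656 and 0.081).

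Lists of carbohydrate breakdown and glycolipid genes lay lower. Lysosomal glycosidases and sulfatases were shifted down (adjusted p = 0.00712, or 0.34 with an estimated correlation), with 15 of 17 members lower and a median of -0.30; none fell over all probe sets or adjusted over the list alone. Genes of glycosphingolipid synthesis and breakdown were shifted down (adjusted p = 0.0103, or 0.285 with an estimated correlation), with 17 of 21 members lower and a median of -0.28. None of these 21 passed over all probe sets, while 1 rose (B4galt5) and 2 fell adjusted over the list alone, or 1 and 4 with the block, and the sulfatide-forming enzyme Gal3st1 was at -1.32 (adjusted p = 0.258 over all probe sets). The fucose list was shifted down (adjusted p = 0.0447, or 0.285 with an estimated correlation, and 0.0653 with the block), with 10 of 14 members lower; none fell over all probe sets, and 1 fell adjusted over the list alone, or 2 with the block. With 1 sample left out, the lysosomal list did not pass without 2 h replicate 1 (0.0739), nor the glycosphingolipid list without non-wounded replicate 1 (0.0539). Leaving out any 1 of the 8 samples but non-wounded replicate 3 ended the fucose call (0.0567 to 0.146).

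Markers of other cell types were measured beside these groups. Dermal fibroblast markers, which include Dcn and Fmod, were shifted up (adjusted p = 0.034, or 0.579 with an estimated correlation), with 7 of 7 higher (5 of 7 with each sample scaled to one median and SD), a median of 0.31 and none past the test over all probe sets or adjusted over the list alone. This shift went with the chemokine, adhesion, EGF family and hyaluronan lists upward and with the lysosomal, glycosphingolipid and fucose lists downward. Of these 7 genes 6 are also in another list, and the brightest, Cxcl12 and Dcn, had mean log2 values of 4.88 and 4.53 in non-wounded and 4.91 and 5.13 in 2 h samples. Neutrophil markers had a median of 0.22 with 7 of 7 higher (adjusted p = 0.0881), or 0.10 with 5 of 7 higher with each sample scaled to one median and SD (0.0609). Their adjusted p was 0.0486 with samples centred on their medians, 0.038 with a term for number 1, 0.0538 with the block, 0.102 in the samples numbered 2 to 4 alone and 0.294 with an estimated correlation. All 7 are also in another list, and the brightest, Il1r2, was at 9.49 in non-wounded and 9.86 in 2 h samples. Adjusted p was 0.283 for endothelial markers (median 0.13, or 0.017 with each sample scaled to one median and SD), 0.352 for Langerhans cell and antigen presentation markers (0.07, or -0.02 with that scaling) and 0.742 for T cell markers (0.01, or -0.15 with that scaling). It was 0.758 for keratinocyte markers (-0.05, or 0.24 with that scaling) and 0.822 for monocyte and macrophage markers (0.11, or 0.0075 with that scaling). The Notch list had an adjusted p of 0.0881 with 12 of 14 members lower. After repeated quantile normalization the EGF family, fucose and fibroblast lists no longer passed (0.0682, 0.0759 and 0.0603), and the fibroblast list did not without 2 h replicate 1 (0.343) or non-wounded replicates 2, 3 or 4 (0.116, 0.0709 and 0.0604). In the samples numbered 2 to 4 alone the EGF family, fucose and hyaluronan lists did not (0.157, 0.142 and 0.0556).

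**Figure D3:**
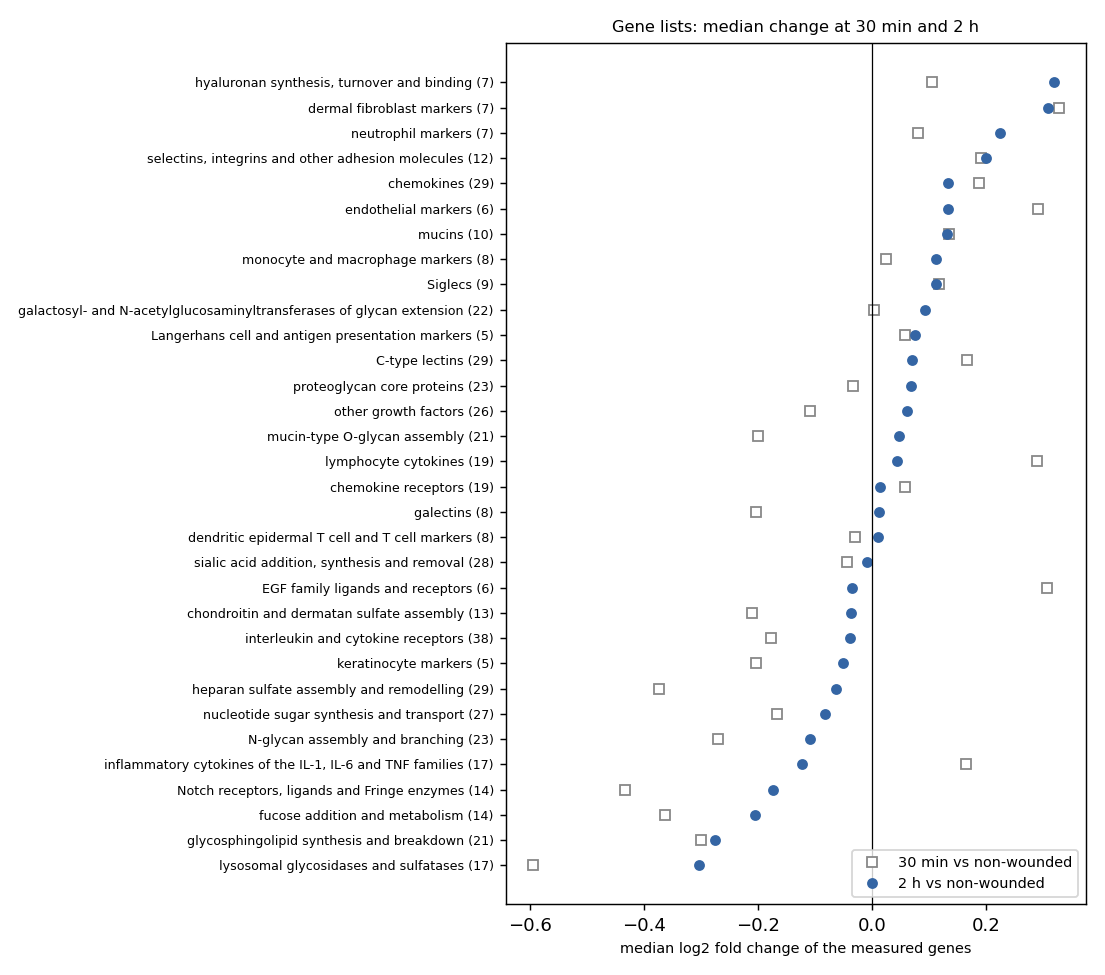
Median log2 fold change against non-wounded samples of each list's measured genes at 2 h (filled circles) and 30 min (open squares), with the number of measured genes in parentheses. Lysosomal glycosidases and sulfatases lie at -0.30 at 2 h and -0.60 at 30 min, and the dermal fibroblast markers at 0.31 and 0.33. In the samples numbered 2 to 4 alone, which are not drawn here, the first list is at -0.25 and -0.31 and the second at 0.11 and 0.16.

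The second comparison asked what had changed 30 min after wounding. No probe set passed in the limma fit with or without the block. At an unadjusted p under 0.05 there were 63 without it and 136 with it, and the smallest adjusted p was 0.735 without the block. Of the 10 named genes with the smallest p, 9 were lower at 30 min. The values below are from the fit without the block, where 1 of the 2 samples at 30 min is numbered 1. That is a larger share than in the non-wounded group, so the narrower range of this sample may enter these values. The 2 unnamed probe sets that fell at 2 h with the block were at log2 -1.32 and -1.03 at 30 min in this fit. Without the samples numbered 1 they were at -0.21 and -0.38, with a single sample at 30 min. Csgalnact1, which starts chondroitin sulfate chains, was at log2 -1.43 ± 0.39 (SE), the sulfatide-forming enzyme Gal3st1 at -1.43 ± 0.41, the galectin Lgals1 at -1.27 ± 0.40, the mannosyltransferase Alg12 at -0.98 ± 0.28 and the uronyl sulfotransferase Ust at -0.85 ± 0.24, each with an adjusted p of 0.735. A second probe set of Ust was at -0.36. The one higher gene of the 10 was Ccl21a at 1.31 ± 0.42 (adjusted p = 0.735). Hbegf was at 0.81 ± 0.58 (0.737). When the 30 min sample numbered 2 was left out, so that the lone 30 min sample was numbered 1, 74 probe sets passed.

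At 30 min 6 lists passed the camera test, and none did with an estimated correlation (each with an adjusted p of 0.634). Lysosomal glycosidases and sulfatases were shifted down (adjusted p = 0.0211, and 0.00813 with the block), with 14 of 17 members lower, among them Arsa at -1.74, and a median of -0.60, or -0.31 in the samples numbered 2 to 4 alone. Genes of glycosphingolipid synthesis and breakdown were also shifted down (0.0314, and 0.0263 with the block), with 17 of 21 lower. Chemokines were shifted up (0.0414, and 0.277 with the block), with 22 of 29 higher and a median of 0.19 that became -0.07 with each sample scaled to one median and SD. That scaling moved the median of all probe sets from 0.04 to -0.09. Shifted up too were lymphocyte cytokines (0.0211, and 0.224 with the block), with 17 of 19 higher and a median of 0.29, or 12 of 19 and 0.08 with that scaling. Dermal fibroblast markers were shifted up beside them (0.0314, and 0.0564 with the block; 7 of 7 higher, median 0.33, or 5 of 7 and 0.19 with that scaling), as were endothelial markers (0.047, and 0.195 with the block; 6 of 6 higher, median 0.29, or 4 of 6 and 0.05 with that scaling). The EGF family passed with the block and not without it (0.0378 and 0.102), and the blocked adjusted p was 0.641 with an estimated correlation. Adjusted over the list alone, no member of these 7 lists rose or fell without the block, while with it 2 glycosphingolipid genes and 1 lysosomal gene fell. The chondroitin and dermatan sulfate list, which did not pass (adjusted p = 0.189), had 2 members that fell, or 1 with the block. Without the 30 min sample numbered 1 the chemokine, fibroblast and endothelial lists did not pass (0.597, 0.552 and 0.324), nor did the lymphocyte cytokines, whose shift was then downward (0.979). Without the other 30 min sample, of the 6 only the lymphocyte cytokines passed (0.0732 to 0.106 for the other 5). Leaving out non-wounded replicate 2, 3 or 4 ended the chemokine and endothelial calls (0.0511 to 0.0855). The glycosphingolipid call ended without non-wounded replicate 1 or 2 (0.0723 and 0.0511) and the fibroblast call without replicate 2 (0.0511). All 6 calls were lost after repeated quantile normalization, with each sample scaled to one median and SD, and without the dim probe sets.

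The last replicated comparison set 2 h directly against 30 min. No probe set passed with limma, with or without the block (27 and 67 at an unadjusted p under 0.05). The genes with the smallest p were higher at 2 h: B4galt5 by log2 1.15 ± 0.24 (SE), Ccl20 by 3.54 ± 0.79, Icam1 by 2.42 ± 0.59 and Hbegf by 2.37 ± 0.58, each with an adjusted p of 0.475, and Vegfa by 1.17 ± 0.30 (0.517). Cxcl2 was higher by 2.65 ± 0.71 and the dendritic cell surface molecule Cd83 by 1.93 ± 0.53, each with an adjusted p of 0.621. In the samples numbered 2 to 4 alone, where a single sample stands for 30 min and is assumed to vary like the others, 2 probe sets passed, Cxcl2 (3.51, adjusted p = 5.85e-05) and NM_020008.1_psr1_at (2.34, 0.00296).

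The samples at 0 h and 4 h had no replicate, so their differences are described without a test. At 4 h, 292 probe sets differed from the non-wounded mean by 1 or more on the log2 scale and lay outside the range of the 4 non-wounded samples, 77 higher and 215 lower. The balance changed with the scaling, to 107 higher and 95 lower after repeated quantile normalization and to 33 higher and 267 lower after median centring. Among the highest were Ccl20 (log2 difference 3.81), Cxcl1 (2.93), Hbegf (2.29), Il1b (2.28), the lipoprotein lipase inhibitor Angptl4 (2.27), B4galt2 (2.01) and Has2 (1.87). The lowest were Il20rb (-3.94), the cytokine Il18 (-3.31), the heparan sulfate epimerase Glce (-3.10), Hnrnpul2 (-3.09), Nagk (-3.01), Hs3st6 (-2.98), Notch1 (-2.97) and Tcea1 (-2.96). Against the non-wounded sample numbered 1 alone, 147 differed by 1 or more, 41 higher and 106 lower. The 4 h sample had the narrower range of the 2 (SD 1.55 against 1.81), and with each sample scaled to one median and SD 81 were higher and 112 lower. Unscaled, Ccl20 was 3.39 higher, Hbegf 2.37 higher and Il20rb was at -2.99, while Il18 was at -1.89, Glce at -1.26 and Hnrnpul2 at -0.88. Medians of the 32 lists were set against 10000 random lists matched on level. Against that sample 3 lay below the 5 or above the 95 percentile and against the non-wounded mean 5 did, where chance gives about 3.2. The 6 lists given here were chosen after their values were seen. The hyaluronan list had a median difference of 0.52 from that sample, at the 99.25 percentile, and of 0.43 from the non-wounded mean, at the 93.30 percentile. The lysosomal list had one of -0.58 from that sample, at the 3.92 percentile, and of -0.85 from the mean, at the 18.63 percentile. The chemokine list was at the 72.19 percentile from that sample (median 0.14) and the 75.27 percentile from the mean (0.36), and lymphocyte cytokines at the 55.12 (0.13) and the 97.75 (0.59). Beside them, dermal fibroblast markers had a median difference of 0.19 from that sample, with 6 of 7 higher, at the 61.35 percentile, and of 0.63 from the mean, with 7 of 7 higher, at the 89.97 percentile. Endothelial markers had one of 0.24 from that sample, at the 66.39 percentile, and of 0.64 from the mean, at the 86.75 percentile, with 5 of 6 higher against either.

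At 0 h, 79 probe sets met the same description, 12 higher and 67 lower, and 11 differed by 1 or more from the non-wounded sample numbered 1. The balance was 38 higher and 44 lower after repeated quantile normalization, 2 and 80 after median centring and 25 and 59 with each sample scaled to one median and SD. The largest positive differences were those of Ccl21a (1.83) and Ccl21c (1.36), which were 1.25 and 0.58 above the non-wounded sample numbered 1. The lowest differences were those of Piga (-2.25), the alarmin Il33 (-2.25) and Prdm1 (-2.14), which were -1.12, -0.32 and -1.29 from that sample. At 0 h Hbegf was at -0.48 and Ccl20 at -0.41 from the non-wounded sample numbered 1.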

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

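The tests of the range of values, of dermal tissue at 2 h and of neutrophil entry were chosen after the results they bear on were seen, as were the fits with a term for the samples numbered 1 and with the samples numbered 2 to 4 alone. In each group of 4 samples, values whose gap to the nearest other sample, as a share of the group's range, exceeded Dixon's critical value were picked out. Of 70 sets of 4 values, 9 were picked out, where chance gives about 1 in 20, and in 7 of the 9 the distant sample was replicate 1.

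The SD of the log2 values was 1.81 in non-wounded replicate 1, against 2.22 to 2.30 in the other 3 samples, and 1.59 in 2 h replicate 1, against 2.19 to 2.23. At 2 h, replicate 1 was low for Cxcl2 (3.83 against 6.58 to 6.76) and Sdc1 (7.15 against 8.88 to 8.89), and high for Fmod (4.65 against 3.36 to 3.49). In the non-wounded group, replicate 1 was low for Csf2rb (3.94 against 5.11 to 5.28) and high for Clec4d (3.87 against 3.03 to 3.07). B4galt5 was 4.60 in non-wounded replicate 3 (4.34 to 4.38 in the others) and Il6 4.17 in 2 h replicate 4 (3.08 to 3.20).

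The first pattern is that the samples numbered 1 stand apart. A change of scale that narrows signal and noise alike is argued against as the whole cause. Quantile normalization gives every sample the same distribution. After it the highest correlation between a sample numbered 1 and a sample numbered 2 to 4 was 0.941. The lowest among the samples numbered 2 to 4 was 0.968. Before normalization these were 0.938 and 0.967. A linear change of scale does not alter this correlation, so the step could only show a curved one. A narrower range of signal with the same or more noise would lower the correlation and remain after this step, so it is left open. The lowest correlation among the samples numbered 1 was 0.916 before normalization. More dermal tissue in the samples numbered 1 stays open as a candidate explanation. After quantile normalization the 7 dermal fibroblast markers were higher in these samples by a median of 0.54, at the 99.7 percentile of 10000 level-matched lists, with 5 of 7 higher. Endothelial markers, which dermis would also bring, were at the 46.4 percentile, and a separate hybridisation batch or another mouse cohort was not tested because the labels give neither.

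The second pattern is that few probe sets passed at 2 h without a term for number 1. A term for number 1 gave 20 probe sets, while a term for number 2, 3 or 4 in its place gave at most 0. This goes with variation shared by the samples numbered 1. The first principal component, with 66.9% of the variance, had already set these samples apart. A term for another number leaves that variance in place, so the outcome is no separate test of this explanation. The 8 non-wounded and 2 h samples, fitted without the others, were split into 4 and 4 in 35 ways. Only the real split gave as many as its 3 probe sets (the highest other split gave 0). These 3, 2 higher and 1 lower, shared 2 with the 3 of the main fit, and Ccl20 was not among them. For their number, chance can be excluded only if the replicate numbers are ignored. The real split is also 1 of only 20 that keep the samples numbered 1 apart. The 8 splits that part all 4 same-numbered pairs are too few for a share under 0.05; the real one gave 20 probe sets with the block and the highest other 0. For the lists, 3 of the 35 splits gave as many as the real 4 in this fit of 8 samples, and the highest other gave 8, so chance cannot be excluded for the number of lists; both other splits kept the samples numbered 1 together on one side.

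The third pattern is the higher 2 h level of inflammatory and EGF family genes (Cxcl1, Cxcl2, Ccl20, Il1b, Il6, Hbegf and Areg), which were taken from those named in advance because they were higher at 2 h; Il1a, the other one measured, was not (-0.41). Whether more dermal tissue in the 2 h samples was the whole cause cannot be decided from these values. The 7 genes were chosen for their 2 h level, and 1 of the 2 samples at 30 min is numbered 1, where the fibroblast markers were higher. The median log2 change of these 7 genes was 0.48 at 30 min and 2.40 at 2 h, a ratio of 0.201 with all 7 smaller at 30 min. The fibroblast markers changed by 0.33 and 0.31, a ratio of 1.06. With Il1a included, which was at -0.70 at 30 min and so further from 0 than at 2 h, the ratio of the named genes was 0.253. In the samples numbered 2 to 4 alone, with a single sample at 30 min, the 8 genes changed by 0.47 and 2.34 and the fibroblast markers by 0.16 and 0.11. Entry of neutrophils cannot be told apart from a rise within resident cells, because the 7 neutrophil markers had a median of 0.2246, all 7 higher, or 0.10 with 5 of 7 higher with each sample scaled to one median and SD, and an adjusted p of 0.0881, or 0.294 with an estimated correlation. A response to wounding, the difference the design names, remains open and was not tested separately.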

How the results depend on the processing

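Alternatives with a term for the samples numbered 1, with the samples numbered 2 to 4 alone, with scaling to one SD, with quantile normalization and the block together, and against the non-wounded sample numbered 1 (also with scaling to one SD) were chosen after the data were seen. Causes of the differences below were not tested beyond the fits themselves.

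At 2 h, 3 probe sets passed in the main design. The replicate block gave 17 and a random replicate block 15, which share the pairing by number, and 12 of the 15 were among the 17. Quantile normalization with the block gave 13. Without a block, 7 passed with quantile normalization, 8 with a trend and robust prior and 130 with array weights. There were 20 with a term for number 1, 38 in numbers 2 to 4, and 0 after median centring or at a threshold of 0.01. Leaving out 1 of the samples compared gave 0 to 11. The 3 probe sets of the main design were among the calls with the fixed and random block, quantile normalization, trend, weights, the term and numbers 2 to 4. At 30 min the count stayed at 0 in each alternative other than leaving out a sample (0 to 74). For 2 h against 30 min the count was 2 with quantile normalization and in numbers 2 to 4, and 1 with the random replicate block, the term for number 1, scaling, and quantile normalization with the block; leaving out 1 sample gave 0 to 9, with 9 without 2 h replicate 1 and 3 without 30 min replicate 2.

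Of the 8 lists at 2 h, 5 passed with quantile normalization, in numbers 2 to 4, with scaling, and with quantile normalization and the block, and 0 with an estimated correlation or fry; leaving out 1 sample gave 3 to 7, with 3 without 2 h replicate 1, 4 without non-wounded replicate 1 and 5 without 2 h replicate 3. Against the 6 lists at 30 min, 3 passed with the replicate block and with quantile normalization and the block (2 of the 6, and the EGF family), and 0 with quantile normalization, without dim probe sets, with scaling, with an estimated correlation or with fry; leaving out 1 sample gave 2 to 5, with 2 without non-wounded replicate 2 (both of the 6) or 30 min replicate 2 (1 of the 6) and 3 without 30 min replicate 1 (2 of the 6). The replicate block changed no other list call or call over all probe sets than those given with the results; adjusted over the list alone it changed the number of called members in 13 lists at 2 h and 4 at 30 min.

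The 79 differences at 0 h became 31 at a minimum of 1.5 and 11 against the non-wounded sample numbered 1, or 21 with scaling to one SD too (64 to 215 with 1 non-wounded sample left out, 215 without replicate 1), and the 292 at 4 h became 146, 147 and 193 (266 to 420). For 0 h and 4 h, with 1 sample each, no blocked fit was run. Their comparison by number is the one with the non-wounded sample numbered 1, without a replicate.

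For named genes at 2 h, 344 values under alternatives other than leaving out a sample kept their direction and side of the threshold, 80 newly passed and 3 no longer did (Hbegf and Ccl20 after median centring, Ccl20 in the groups compared alone, adjusted p = 0.0619). One changed sign: Klrk1 ran from -0.0845 to 0.0094 with 1 sample left out, the latter without non-wounded replicate 1, against -0.05. RMA values give no signal over background, so what dim probe sets limit is not known here.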

Other observations

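The tests on recurrence at 2 h were chosen after the result was seen, and those at 0 h and 4 h and the families below after the main results. The genes named in the next sentences were chosen after their values were seen. In the samples numbered 2 to 4 alone, the 38 probe sets past the limma threshold at 2 h held further genes than those already described. Among the 23 that rose were Cd83, a surface molecule of activated dendritic cells (log2 1.97, adjusted p = 0.0104), the activin antagonist Fst (1.22, 0.0392), S100a10 (1.17, 0.0385), the cytokine receptor subunit Csf2rb (1.00, 0.0284) and Wnt10a (0.88, 0.044). Among the 15 that fell were the arylsulfatase Arsa (-0.99, 0.00728), the sialidase Neu3 (-0.79, 0.0194) and the N-acetylglucosamine kinase Nagk (-0.69, 0.0222), and Fut1 (-1.25, 0.0104).

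Families put together after the data were seen, some of which share members with the fixed lists, did not pass the camera test at 2 h or 30 min. Of the Frizzled receptors 8 of 9 were lower at 2 h (median -0.17, adjusted p = 0.543). Of the Slc35 family, taken by symbol and holding nucleotide sugar transporters among others, 15 of 21 were lower (median -0.15, 0.543). Neither median changed sign with another scaling. At 30 min, 16 of 22 fibroblast growth factors (median 0.20, or -0.03 with each sample scaled to one median and SD), 16 of 20 bone morphogenetic proteins and growth differentiation factors (11 of 20 with that scaling), and 9 of 10 Ly49 receptors (5 of 10 with that scaling) were higher, each with an adjusted p of 0.0701, or 0.883 with an estimated correlation.

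A hypothesis is that the 2 h change seen in the samples numbered 2 to 4 also occurs in the separate samples numbered 1, which took no part in choosing those probe sets. In the 2 h sample numbered 1, the 23 risen probe sets lay above the non-wounded sample numbered 1 by a median of 0.6702, with 18 of 23 higher, above all of 10000 level-matched lists. The 15 fallen ones were lower by value in 13 of 15, but their median of -0.61 lay at the 10.6 percentile of level-matched lists, so the test goes with the hypothesis for the rises and leaves the falls open.

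A second hypothesis is that the change is present at 4 h. There the risen probe sets had a median of 0.8364, with 21 of 23 higher, above all of 10000 level-matched lists. This goes with the hypothesis for the rises in this single sample. The fallen ones had a median of -1.40, with 14 of 15 lower, above only 1 of 10000 lists. They were also low in the 30 min sample numbered 1 (-1.55) and less so in the 2 h sample numbered 1 (-0.61, 10.6 percentile). Whether the falls at 4 h belong to the 2 h change is therefore left open. At 0 h the risen probe sets had a median of 0.1157, with 12 of 23 higher, at the 79.4 percentile, and the fallen ones one of -0.13, at the 4.1 percentile, so presence at 0 h could not be decided. At 30 min 11 of the 23 risen probe sets were higher in the sample numbered 1 (median -0.07, 64.0 percentile), while the fallen ones had a median of -1.55, below all of 10000 lists. Each of these is a comparison of 2 libraries with no replicate. The 30 min, 2 h and 4 h samples also had a narrower range than the non-wounded sample numbered 1.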
